A study of Homo sapiens with 12 samples.

How the data were processed

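RNA sequencing read counts per gene were analysed for 12 libraries of the established gastric cancer cell line NUGC-4. The deposited matrix holds whole read counts per gene, 60623 genes by 12 libraries, with no normalization. Per the submitters' processing notes, the reads passed through Trimmomatic, FastQC, HISAT2, featureCounts and DESeq2, with builds hg38 and GRCh38. Versions, the annotation release and the strand setting of the counting were not given. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a directional kit. The description label mentions adipogenic differentiation for every sample, which the other labels do not, so a list of adipocyte markers was included among the lists.

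Libraries were grouped by the treatment label into control, IN10018, crizotinib and combination, with 3 in each. Column totals ran from 13691844 to 20489708 reads. All 12 libraries entered 1 fit with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group (17096 genes tested) and a robust quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 in a comparison were called. The 6 comparisons were each treatment against control, the combination against each single drug, and the interaction of the 2 drugs on the log2 scale. Because 1 fit was used, the libraries outside a comparison also set its estimate of spread, with a common biological coefficient of variation of 0.139. DESeq2 1.42.0 and limma-voom with limma 3.58.1 were run as other tools. Limma-voom used the same filtered genes. DESeq2 was run without that filter and gave a p-value for 35677 genes, so its counts cover a different set of genes.

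Gene types, positions, lengths and GC content came from GENCODE 29 on GRCh38, which held 96.52% of the deposited gene identifiers and gave GC content for 98.65% of tested genes. Symbols are those of the deposited matrix. Reads shared between paralogs or pseudogenes, as for FTH1 and RPL13P12, and antisense genes carry more doubt, because the counting rules were not stated.

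Gene lists were written from general knowledge and tested with camera at a preset correlation of 0.01, over the 37 lists with at least 5 tested members. Camera with an estimated correlation and fry were alternatives. List members were also counted with p-values adjusted over the list alone. Lists, comparisons, tests and the naming rule were fixed before the data were examined.

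Genes named in the text follow a rule. For its first part, genes needed an adjusted p under 0.05 and a mean log2 CPM of at least 1. Outside the interaction, every library of one group also had to lie above every library of the other. Among these genes the 6 largest changes each way were taken. Up to 4 members with the smallest p, called or not, were added from each list that was called or had at least 5 called members. Genes of the series title were taken in the comparisons against control whether called or not, and up to 4 members with the smallest p from the YAP/TAZ-TEAD and thioredoxin lists in every comparison. A gene named by the rule in 1 comparison is also followed in others. The text leaves out some genes named by the rule.

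Alternatives were DESeq2 size factors, library totals, no filter, a stricter filter (at least 1 CPM by library totals in 3 libraries and 100 reads in all), a replicate block, only the 6 libraries compared, a 2-fold minimum, genes at high expression only for the correlations, both other tools, and leaving out each library in turn. Chosen after seeing the data were an offset for GC content and length, removal of mitochondrially encoded genes, removal of the libraries numbered 2 of crizotinib and combination, a covariate for the leading axis within groups, a block within 6 libraries, and list tests against protein-coding genes.

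Whether replicate numbers pair libraries was checked by correlating residuals between groups. Same-number correlations for crizotinib and combination were 0.22, 0.62 and 0.27, but crizotinib library 1 correlated more highly, at 0.42, with a combination library of another number. Between control and each treatment, numbers 2 and 3 also correlated above every other number (0.043 to 0.156) and number 1 did not. The labels do not say what the numbers mark, so the comparisons carry no block, and a block was run as an alternative.

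The procedure was tested on simulated data, where 100 genes were changed by 1 and 100 by 2 on the log2 scale. Each gene was drawn independently with its estimated spread, taken as equal in all 12 libraries. The real libraries have correlated genes and unequal spread between groups, so the rates below hold only for the simulated setting. EdgeR recovered 77 and 98% for IN10018 against control, 75 and 100% for crizotinib against control and 73 and 100% for the combination against control. It recovered 78 and 98% for the combination against IN10018, 81 and 98% for the combination against crizotinib and 54 and 93% for the interaction. False calls made up 3.3 to 6.5% of edgeR calls. For the combination against control DESeq2 recovered 76 and 99% with 15.5% false calls, limma-voom 72 and 99% with 6.0%, and edgeR with a block 74 and 99% with 4.4%. The simulated DESeq2 run used the 17096 filtered genes, unlike the run on the real counts. A list moved by 0.5 was called by camera (adjusted p = 9.0e-51) and with an estimated correlation (5.5e-06), and 0 of 35 unchanged lists were called. A simulated GC trend gave 6603 false calls without the offset and 0 with it. Principal components used log2 CPM with a prior count of 2.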

Results

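Gene-level read counts were available for 12 RNA libraries of NUGC-4, a diffuse gastric cancer line labelled wild type. The cells were treated for 24 h with 1 µM IN10018, with 1 µM crizotinib, with both drugs, or left as control, with 3 libraries in each of the 4 groups. IN10018 inhibits focal adhesion kinase (FAK, encoded by PTK2), and crizotinib inhibits the receptor kinases ALK, MET and ROS1. Total reads were 14361383, 17144114 and 20489708 in control libraries 1 to 3. They were 16489986, 20059012 and 14908752 with IN10018, 16845001, 16610562 and 15634366 with crizotinib, and 15714156, 13691844 and 15420023 with the combination. Levels are given as mean CPM (counts scaled to the library total times its TMM factor) with the SD over n = 3 libraries. Changes are given as log2 fold changes with an approximate SE. This SE is the absolute change divided by the square root of its F value in the 12-library fit. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

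ROS1, a crizotinib target named in the series title, had 0 reads over the 12 libraries, which allows a level of up to 0.0152 CPM over all of them (3 counts of the total reads without TMM factors, counting error only). The other drug targets were read in every group. In control, MET (ENSG00000105976, GRCh38 chromosome 7, 116672390 to 116798386) had 745 ± 43.9 CPM and PTK2 (ENSG00000169398, chromosome 8, 140657900 to 141002216) had 355 ± 3.96 CPM. ALK had 3.99 ± 0.468 CPM. CDH1, the E-cadherin gene whose loss the series title concerns, had 5.21 ± 0.858 CPM in control, and YAP1 (ENSG00000137693, chromosome 11, 102110461 to 102233423) had 78.6 ± 3.50 CPM.

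The libraries separated mainly by crizotinib. The first principal component held 67.2% of the variance and the second 8.2%. Crizotinib library 2 stood apart from its group on the first component, with a score of 57.8 against -4.6 and 10.3 for crizotinib libraries 1 and 3 and 56.3, 91.4 and 37.8 for the combination libraries. The share of reads from mitochondrially encoded genes was 11.2, 10.997 and 11.9% in control and 12.3, 12.7 and 11.5% with IN10018. It was 13.3, 5.2 and 9.5% with crizotinib and 7.0, 4.3 and 6.6% with the combination, with the lowest crizotinib value in library 2.

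**Figure D1:**
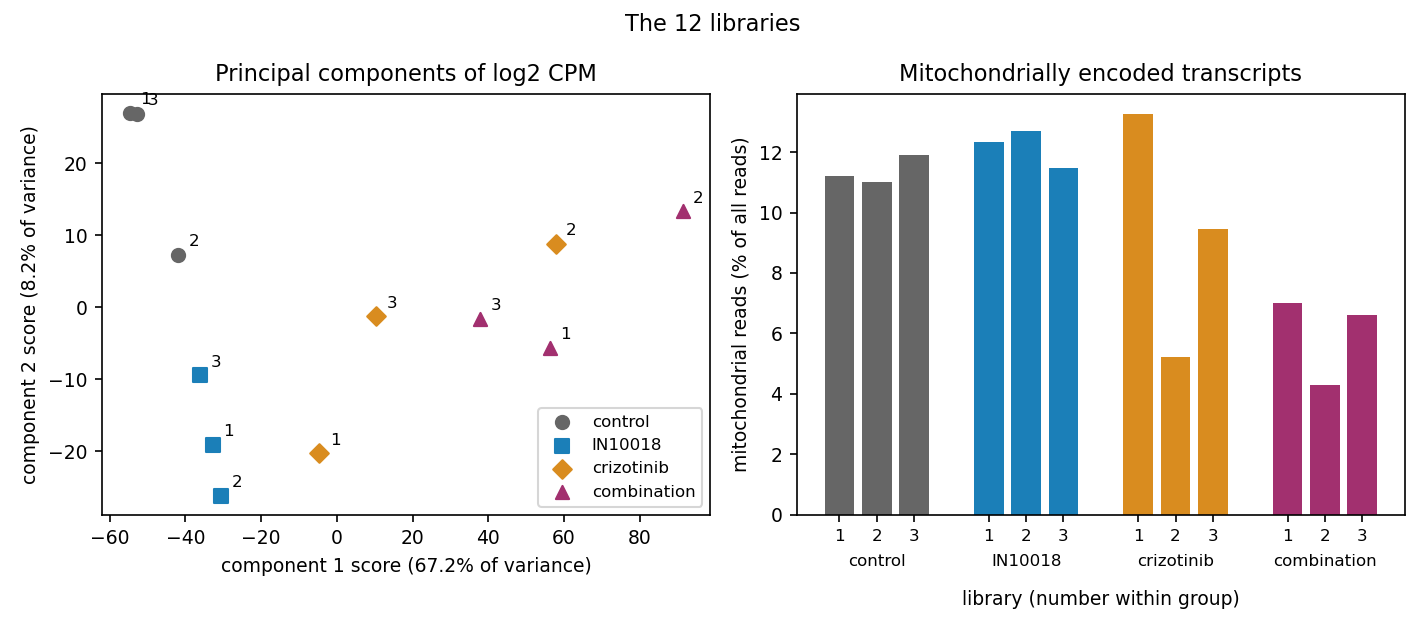
Scores on the first and second principal components, with points as libraries, and percent of reads from mitochondrially encoded genes, with bars as libraries, by group. Crizotinib library 2 scored 57.8 on the first component and held 5.2% mitochondrially encoded reads, within the combination range for both measures.

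The comparison of IN10018 with control addressed what this drug alone changed. FAK activity itself was not measured in these data. Several rapidly inducible transcription factors and feedback regulators fell, while 10 of 22 listed immediate early genes were not called. ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777), a stress-induced transcription factor, went from 23.4 ± 2.78 to 2.89 ± 0.446 CPM, a log2 fold change of -3.02 ± 0.21 (edgeR adjusted p = 1.2e-05). TRIB1 (ENSG00000173334, chromosome 8, 125430321 to 125438405), a pseudokinase adaptor, went from 260 ± 33.0 to 79.4 ± 4.90 CPM (-1.71 ± 0.13, adjusted p = 2.2e-05). The orphan nuclear receptor NR4A2 (ENSG00000153234, chromosome 2, 156324432 to 156342348) fell by 1.39 ± 0.13 on the log2 scale (adjusted p = 0.00021), and EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315) by 1.29 ± 0.15 (adjusted p = 0.0020). PPP1R15A, a phosphatase subunit that ends the integrated stress response, changed by -1.49 ± 0.17, and FOSB (ENSG00000125740, chromosome 19, 45467995 to 45475179) by -1.31 ± 0.16. The long non-coding RNA NEAT1 (ENSG00000245532, chromosome 11, 65422774 to 65445540), the scaffold of paraspeckles, rose from 720 ± 158 to 1798 ± 245 CPM, a change of 1.32 ± 0.17 (adjusted p = 0.0039). These 7 genes remained called in every alternative run for this comparison.

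Other IN10018 calls were lost when single libraries were left out, with small changes in fold. In a fit of only the 6 libraries compared, 83 of the 85 genes called and tested in both were called the same way. NR4A1 (-1.50 ± 0.20) and the coactivator CITED2 (-0.93 ± 0.12) were no longer called without IN10018 library 2, at -1.46 and -0.87. KLF4 (-1.57 ± 0.29) was not called without control library 1 (-1.43), control library 3 (-1.55), IN10018 library 1 (-1.71), IN10018 library 2 (-1.43) or IN10018 library 3 (-1.56). CCN1 (ENSG00000142871, chromosome 1, 85580761 to 85583962), a matricellular target of YAP, went from 150 ± 7.90 to 97.0 ± 9.31 CPM (-0.63 ± 0.12, adjusted p = 0.039). Leaving out any one of the 3 control or 3 IN10018 libraries ended the CCN1 call, as did leaving out crizotinib library 3, combination library 1 or combination library 3, with values between -0.67 and -0.56. The antisense or intergenic transcripts LINC01355 (1.22 ± 0.20) and TMEM161B-AS1 (1.09 ± 0.18) rose. Without control library 1, control library 3, IN10018 library 1 or IN10018 library 2 they were not called, at 1.12 to 1.22 for LINC01355 and at 1.13, 0.98, 1.07 and 1.03 for TMEM161B-AS1.

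The genes of the series title had no call in this comparison. PTK2 differed by -0.06 ± 0.15 (edgeR adjusted p = 0.90), MET by -0.20 ± 0.16 (0.71), YAP1 by -0.11 ± 0.15 (0.84) and TXNRD1, the cytosolic thioredoxin reductase, by -0.11 ± 0.14 (0.81). CDH1 differed by -0.49 ± 0.20 (0.37). The YAP target CCN2 differed by -1.68 ± 0.39 without passing the threshold (0.094).

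With edgeR, 59 genes were higher and 27 lower with IN10018 among 17096 tested, 30 and 19 of them at least 2-fold, and 1886 genes had an unadjusted p under 0.05. DESeq2, run without the filter on 35677 genes, called 114 higher and 67 lower, and limma-voom 39 and 24. A fit of the 6 control and IN10018 libraries alone, without the more variable crizotinib and combination libraries, called 1314 higher and 879 lower. The count of higher genes fell to 2 without control library 1, 1 without control library 3, 2 without IN10018 library 1, 1 without IN10018 library 2, 39 without IN10018 library 3 and 36 without combination library 1, and was 169 without crizotinib library 2. The count of lower genes was 14, 17 and 13 without control libraries 1, 2 and 3, 10, 6 and 13 without IN10018 libraries 1, 2 and 3, and 54 without crizotinib library 2. Long non-coding genes, a class examined after the values were seen, held 33 of the higher calls and 1 of the lower, with a median change of 0.35 over 2618 genes, 79.7% of them above 0. Protein-coding genes held 13 higher and 26 lower calls, with a median of -0.06.

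Of 37 gene lists fixed beforehand, camera called 24 in this comparison, all as lower, with medians from -0.98 to -0.07. Camera compares each list with all other tested genes, among them the non-coding genes that sat higher. Against protein-coding genes alone, 15 of the 24 lists were called. With an estimated correlation between genes, 8 were called. With both changes together only the immediate early list was called (adjusted p = 0.00012). The ERK, NF-kB and STAT3 lists then had 0.064, the FOXO list 0.070, the ATF4 and p53 lists 0.12 and the cholesterol list 0.13. Of 22 immediate early genes, which respond to growth signals within minutes, 12 fell, 0 rose and 10 were not called (16 lower and 1 higher adjusted over the list alone). Their median was -0.98 (camera adjusted p = 4.1e-54, 0.0002 with an estimated correlation). In the list of ERK pathway output, EGR1 was the only 1 of 24 genes called, against 6 adjusted over the list alone (median -0.20, adjusted p = 4.1e-07, 0.040 with an estimated correlation). The NF-kB and cytokine list had 2 of 20 genes lower, the NF-kB inhibitor TNFAIP3 and the chemokine CXCL2 (median -0.15, adjusted p = 0.00026, 0.037 with an estimated correlation). The TNFAIP3 call was lost without any one of the 6 control and IN10018 libraries (-1.703 to -1.201). The CXCL2 call was lost without control library 2 or 3, any IN10018 library, crizotinib library 1 or 3, or combination library 1 or 3 (-1.01 to -0.82). Among 15 STAT3 targets only JUNB was called, at -0.87 ± 0.16, and not without control library 1 (-0.94) or 3 (-0.71), IN10018 library 1 (-0.94), 2 (-0.78) or 3 (-0.87), or crizotinib library 3 (-0.84). The STAT3 list had a lower call (median -0.17, adjusted p = 0.00014, 0.037 with an estimated correlation). The ATF4 list was called (median -0.13, adjusted p = 4.9e-05, 0.045 with an estimated correlation) with ATF3 as its only called member of 31. In the FOXO list only TRIB1 and CITED2 of 22 were called (median -0.13, adjusted p = 1.2e-05, 0.040 with an estimated correlation), and the p53 list of 29 genes was called lower (median -0.07, adjusted p = 0.0036, 0.040 with an estimated correlation). The cholesterol synthesis list was called with no member called (median -0.11, adjusted p = 0.0051, 0.045 with an estimated correlation).

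The remaining 16 lists had medians between -0.19 and -0.09 and adjusted p between 0.062 and 0.35 with an estimated correlation. The 20 tested YAP/TAZ-TEAD targets were among them, with CCN1 as the only fall and 19 genes not called, 2 lower adjusted over the list alone (median -0.13, camera adjusted p = 0.00039, 0.068 with an estimated correlation). None of the 23 thioredoxin and peroxiredoxin genes was called (median -0.10, adjusted p = 0.022, 0.12 with an estimated correlation), and the list call ended without control library 3 (-0.09) and against protein-coding genes. The 44 S phase genes had no call (median -0.19, adjusted p = 2.5e-08, 0.062 with an estimated correlation). Their member MCM2, a subunit of the replicative helicase, differed by -0.41 ± 0.13.

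The comparison of crizotinib with control addressed the effect of the kinase inhibitor alone. Inducible genes called with IN10018 also fell with crizotinib, as did MET, the YAP target CCN1 and the replication gene RRM1. FOSB went from 483 ± 102 to 23.3 ± 4.72 CPM (-4.38 ± 0.18, edgeR adjusted p = 1.6e-08). ATF3 reached 0.664 ± 0.232 CPM (-5.13 ± 0.25, adjusted p = 6.7e-08). FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230) went from 945 ± 116 to 145 ± 24.1 CPM (-2.71 ± 0.19, adjusted p = 2.5e-06). TRIB1 changed by -2.57 ± 0.13, PPP1R15A by -3.11 ± 0.19, NR4A2 by -2.15 ± 0.13, EGR1 by -2.03 ± 0.15 and KLF4 by -4.39 ± 0.39. NEAT1 rose to 3072 ± 316 CPM, a change of 2.09 ± 0.17 (adjusted p = 1.3e-05). The stress-responsive coregulator NUPR1 rose by 2.12 ± 0.31, the mTOR inhibitor DDIT4 by 1.11 ± 0.12 and the transcriptional repressor BCL6 by 1.26 ± 0.13.

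Of 30 receptor tyrosine kinases and ligands 10 fell, 3 rose and 17 were not called, the same counts adjusted over the list alone, and the list was not called (median -0.06, camera adjusted p = 0.11, 0.28 with an estimated correlation). MET went from 745 ± 43.9 to 366 ± 77.6 CPM (-1.03 ± 0.16, edgeR adjusted p = 0.0016). KIT changed by -1.35 ± 0.25 and EGFR by -1.07 ± 0.22. PTK2 went to 238 ± 57.7 CPM (-0.58 ± 0.15, adjusted p = 0.012). The YAP-related factors TEAD1 (-0.87 ± 0.15) and WWTR1 (-0.66 ± 0.13) fell. YAP1 fell by 0.54 ± 0.15 on the log2 scale (adjusted p = 0.017), and was no longer called without control library 1 (-0.49). TXNRD1 (ENSG00000198431, chromosome 12, 104215779 to 104350305) went from 437 ± 16.5 to 299 ± 55.5 CPM (-0.55 ± 0.14, adjusted p = 0.011). TXNIP, which binds thioredoxin, rose by 0.41 ± 0.11 and was no longer called without control library 2 (0.32). TXN itself differed by -0.25 ± 0.11 without passing the threshold (adjusted p = 0.096). ALK fell by 0.74 ± 0.21, a call lost without control library 1 (-0.66) or crizotinib library 3 (-0.52). CDH1 fell by 0.67 ± 0.20, a call lost without control library 1 (-0.61), control library 3 (-0.63) or crizotinib library 3 (-0.64). With the main axis of variation within groups as a covariate, PTK2 (-0.18), YAP1 (-0.12), TXNRD1 (-0.19) and KIT (-0.70) were no longer called.

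**Figure D2:**
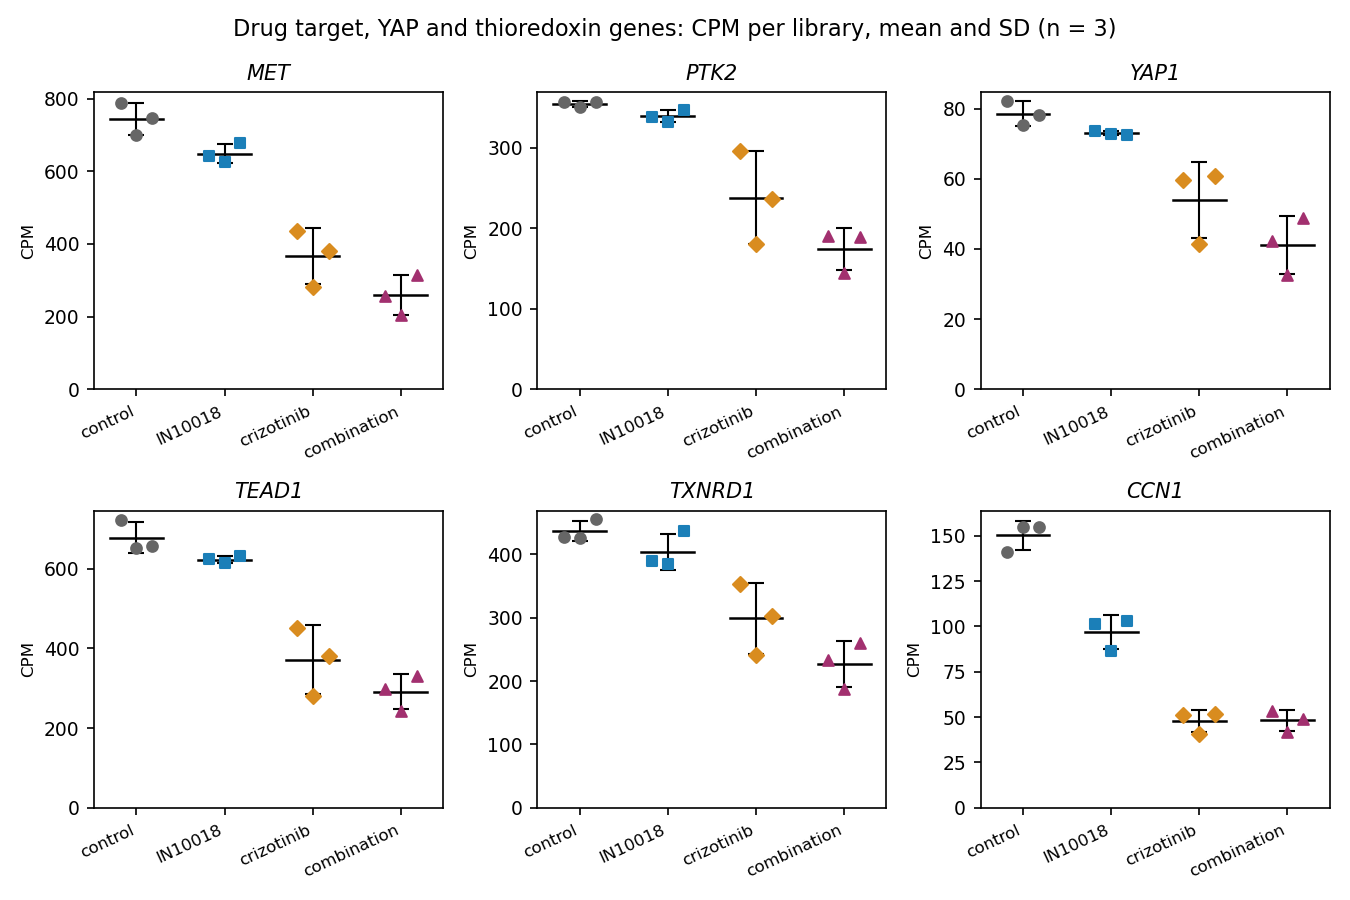
Levels in CPM on a linear axis of genes tied to the series title, with points as libraries and group means with the SD. MET fell from a mean of 745 CPM in control to 366 with crizotinib and 259 with the combination.

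With crizotinib, edgeR called 3421 genes higher and 3014 lower, 1205 and 246 of them at least 2-fold. DESeq2 called 2797 and 3725, limma-voom 3159 and 3207, and 8379 genes had an unadjusted p under 0.05. Higher calls numbered 1766 without control library 1, 1354 without control library 3 and 1770 without crizotinib library 2. Lower calls numbered 1372 without control library 1 and 1876 without crizotinib library 2. With the within-group axis as a covariate 1103 higher and 1066 lower genes were called. After an offset for GC content and length, 3899 of the 6435 genes were called the same way and 3 the opposite way. Scaling by library totals in place of TMM moved the median of all genes by 0.124 and gave 4827 higher and 1948 lower genes. Of the 2618 long non-coding genes, 730 rose and 74 fell (median 0.49).

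Among the lists, 16 of 22 immediate early genes fell and 6 were not called, with 17 lower and 1 higher adjusted over the list alone (median -1.44, camera adjusted p = 7.4e-34, 0.0018 with an estimated correlation). Of 44 S phase genes 35 fell and 9 were not called, 36 lower adjusted over the list alone (median -0.55, adjusted p = 2.6e-16, 0.045 with an estimated correlation). They included the ribonucleotide reductase subunits RRM1 (-0.75 ± 0.09) and RRM2 (-1.205 ± 0.18), the ubiquitin ligase subunit DTL (-1.08 ± 0.13) and MCM2 (-0.91 ± 0.14). Of 57 genes of G2 and mitosis 39 fell, 2 rose and 16 were not called, with 42 and 2 adjusted over the list alone. The cytokinesis regulator ECT2 (-1.15 ± 0.17), the cyclin CCNA2 (-0.91 ± 0.15) and ANLN (-0.97 ± 0.17) were among those lower (median -0.39, adjusted p = 5.6e-12, 0.23 with an estimated correlation). The ERK output list had 16 of 24 genes lower and 1 higher, the same counts adjusted over the list alone (median -0.46, adjusted p = 2.6e-07, 0.045 with an estimated correlation), with PHLDA1 at -0.94 ± 0.13. Of 20 YAP/TAZ-TEAD targets 10 fell and 10 were not called, 11 lower adjusted over the list alone (median -0.35, adjusted p = 2.5e-06, 0.045 with an estimated correlation). CCN1 changed by -1.65 ± 0.13, AMOTL2 by -0.81 ± 0.09, EMP1 by -1.57 ± 0.18 and CCN2 by -3.29 ± 0.49. With an estimated correlation and against protein-coding genes alone, the immediate early list remained called (adjusted p = 0.0031), while the S phase, ERK and YAP/TAZ-TEAD lists did not (0.10 for each).

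Genes of cytosolic ribosomal proteins moved the other way, with 29 of 50 higher, none lower and 21 not called, 35 higher adjusted over the list alone (median 0.34, camera adjusted p = 0.00014, 0.41 with an estimated correlation). RPL13A rose by 0.72 ± 0.18 and RPL18 by 0.92 ± 0.23. In the focal adhesion list 13 of 30 genes fell, 3 rose and 14 were not called, the same counts adjusted over the list alone, with LIMS1 at -0.77 ± 0.15, ITGA6 at -0.60 ± 0.13 and PARVA at -0.55 ± 0.10 (median -0.28, adjusted p = 0.019, 0.32 with an estimated correlation). The unfolded protein response list had 11 of 26 lower and 1 higher, 13 and 1 adjusted over the list alone, and lost its call without crizotinib library 1 (median -0.30, then -0.21; 0.32 with an estimated correlation). The heat shock list had 5 of 19 lower, HSPH1 at -0.62 ± 0.11 (-0.24 and not called after an offset for GC content and length) among them, and 1 higher (median -0.21, 0.38 with an estimated correlation). Its call was lost without control library 3 (-0.22) or crizotinib library 1 (-0.12), and under library totals (-0.08). The p53 list had 9 of 29 lower, with MDM2 at -0.54 ± 0.12 (-0.16 and not called with that offset), and 3 higher (median -0.25, 0.17 with an estimated correlation). Its call was lost without control library 2 (-0.21), crizotinib library 1 (-0.29) or crizotinib library 3 (-0.17), and under library totals (-0.12). No mitochondrially encoded gene was called (list median -0.48, adjusted p = 0.043, 0.61 with an estimated correlation), and the list call was lost without crizotinib library 2 (-0.13) or control library 3 (-0.51). The median of that list turned to 0.39 with the within-group axis as a covariate. Against protein-coding genes alone the focal adhesion, unfolded protein response, heat shock, p53 and mitochondrially encoded lists were not called. In the thioredoxin list 6 of 23 genes rose, 2 fell and 15 were not called, with the peroxiredoxin PRDX5 at 1.18 ± 0.30, a call lost without crizotinib library 2 (0.73). The thioredoxin list itself was not called (median -0.14, adjusted p = 0.55).

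The comparison of the combination with control addressed the joint effect. FOS fell from 945 ± 116 to 13.0 ± 4.40 CPM (-6.18 ± 0.23, edgeR adjusted p = 1.4e-09) and FOSB from 483 ± 102 to 2.70 ± 0.278 CPM (-7.48 ± 0.22, adjusted p = 1.4e-10). ATF3 (-5.15 ± 0.26), KLF4 (-6.31 ± 0.50), PPP1R15A (-3.79 ± 0.20) and EGR1 (-2.75 ± 0.16) fell. NEAT1 reached 4519 ± 773 CPM. The genes with the largest rises by the naming rule included SPATC1 (3.56 ± 0.41), the tendon transcription factor gene SCX (3.17 ± 0.40) and MUC6 (3.06 ± 0.36, adjusted p = 5.9e-05), a gastric gland mucin that went from 2.62 to 22.01 CPM. NUPR1 rose by 2.57 ± 0.31 and BCL6 by 1.48 ± 0.13.

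Of the 15 tested genes of the series title 9 fell, 3 rose and 3 were not called with the combination. MET reached 259 ± 54.2 CPM (-1.52 ± 0.16, edgeR adjusted p = 3.9e-05) and PTK2 175 ± 25.9 CPM (-1.02 ± 0.15, adjusted p = 0.00014). YAP1 reached 41.2 ± 8.23 CPM (-0.93 ± 0.16, adjusted p = 0.00026), TEAD1 changed by -1.22 ± 0.15 and WWTR1 by -0.96 ± 0.13. TXNRD1 went to 227 ± 36.5 CPM (-0.94 ± 0.14, adjusted p = 0.00014). TXN fell by 0.31 ± 0.11 (adjusted p = 0.028), a call lost under library totals (-0.13) and without control library 1 (-0.32), control library 3 (-0.31) or combination library 2 (-0.26), and it stood at 0.10 with the within-group axis as a covariate. TEAD3 rose by 0.41 ± 0.12 but stood at -0.17 after an offset for GC content and length. PTK2B (-0.19 ± 0.09), TEAD2 (0.20 ± 0.14) and TEAD4 (0.16 ± 0.17) were not called. TXNIP rose by 0.31 ± 0.11, a call lost without any control library or combination library 3 (0.23 to 0.34). MST1R rose by 0.27 ± 0.11, a call lost without any control or IN10018 library, combination library 1 or combination library 2 (0.17 to 0.32), and stood at -0.15 with the offset. CDH1 changed by -0.87 ± 0.21, ALK by -0.99 ± 0.21 and EGFR by -1.69 ± 0.22. With the within-group axis as a covariate, PTK2 (-0.32), YAP1 (-0.21), TXNRD1 (-0.32), CDH1 (-0.60) and KLF4 (-3.16) were no longer called.

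With the combination, edgeR called 5761 genes higher and 4968 lower, 2889 and 1437 at least 2-fold. DESeq2 called 5097 and 5378 and limma-voom 5686 and 4985. An edgeR fit of the 6 control and combination libraries alone called 5220 higher and 5133 lower, with a smallest adjusted p of 3.7e-08. With the within-group axis as a covariate 882 and 933 genes were called. After the offset for GC content and length, 6940 of the 10729 genes were called the same way and 342 the opposite way. Scaling by library totals moved the median by 0.179 and gave 7113 higher and 3763 lower. Of the long non-coding genes, 1151 rose and 193 fell (median 0.64). Of 22 immediate early genes 18 fell, 3 rose and 1 was not called, the same counts of calls adjusted over the list alone (median -1.69, camera adjusted p = 2.1e-19, 0.013 with an estimated correlation). The S phase list had 35 of 44 lower and 1 higher, 37 and 1 adjusted over the list alone, with DTL at -1.51 ± 0.14, RRM2 at -1.82 ± 0.19 and MCM2 at -1.49 ± 0.14 (median -0.70, adjusted p = 4.3e-13, 0.075 with an estimated correlation). The list of G2 and mitosis had 42 of 57 lower and 3 higher, with ECT2 at -1.73 ± 0.18 and CCNA2 at -1.40 ± 0.15 (median -0.59, adjusted p = 1.4e-10, 0.33 with an estimated correlation). Of 20 YAP/TAZ-TEAD targets 13 fell, 1 rose and 6 were not called, 14 and 1 adjusted over the list alone (median -0.55, adjusted p = 0.00031, 0.16 with an estimated correlation). CCN1 changed by -1.64 ± 0.13, CRIM1 by -0.90 ± 0.11 and the membrane repair gene MYOF by -1.33 ± 0.16. The ERK output list had 13 of 24 lower and 2 higher (median -0.56, adjusted p = 0.00045, 0.22 with an estimated correlation).

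Of the 13 mitochondrially encoded genes, 12 fell with the combination and 1 was not called, the same counts adjusted over the list alone (median -1.40, camera adjusted p = 0.0007, 0.48 with an estimated correlation). MT-ATP8 changed by -3.25 ± 0.58, MT-ND4L by -2.13 ± 0.39 and MT-ND2 by -1.996 ± 0.42. With the within-group axis as a covariate the list median was 0.26 and MT-ND2 stood at 0.30. Ribosomal protein genes had 39 of 50 higher and 2 lower, 39 and 3 adjusted over the list alone (median 0.46, adjusted p = 0.00016, 0.48 with an estimated correlation), with RPL18 at 1.45 ± 0.23 and RPS15 at 1.19 ± 0.20. The focal adhesion list had 17 of 30 lower and 7 higher (median -0.53, adjusted p = 0.013, 0.41 with an estimated correlation), with the integrin genes ITGA1 (-1.49 ± 0.21) and ITGA2 (-1.24 ± 0.18) and the integrin activator FERMT2 (-1.21 ± 0.17). The unfolded protein response list had 15 of 26 lower and 4 higher (median -0.36, adjusted p = 0.038, 0.48 with an estimated correlation), with SSR1 at -0.99 ± 0.15. Its call was lost without combination library 1 (-0.36) and under library totals (-0.18). Against protein-coding genes alone the focal adhesion and unfolded protein response lists were not called. In the thioredoxin list 11 of 23 genes fell, 7 rose and 5 were not called, the same counts adjusted over the list alone, and the list was not called (median -0.16, adjusted p = 0.55). PRDX5 rose by 1.82 ± 0.31, the methionine sulfoxide reductase MSRB1 rose by 0.92 ± 0.17 (0.17 and not called with the offset) and the mitochondrial PRDX3 changed by -1.06 ± 0.20.

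**Figure D3:**
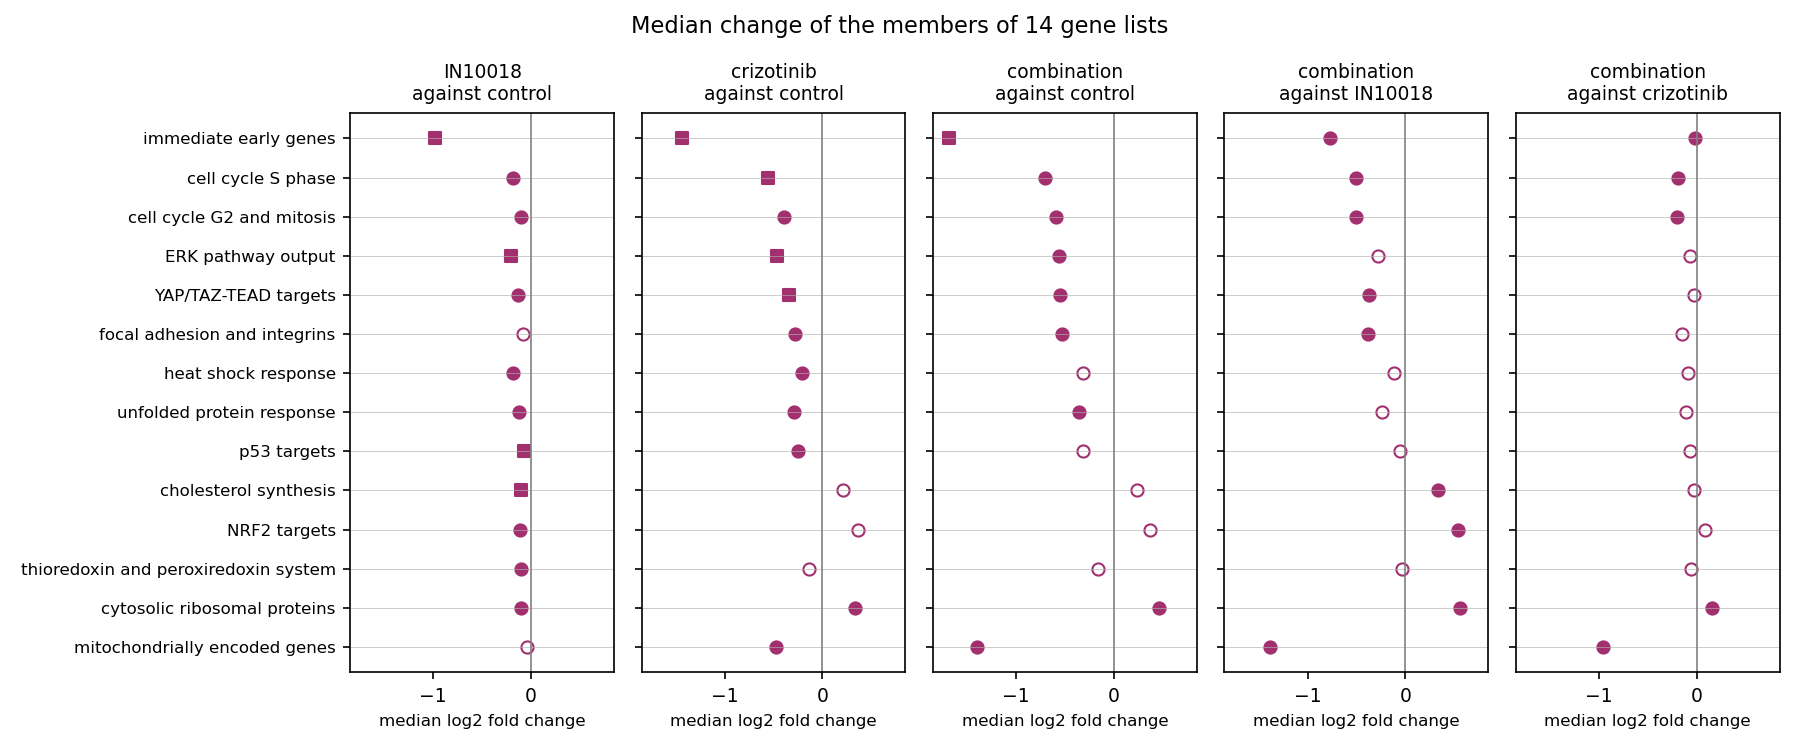
Median log2 fold change of selected gene lists in each comparison. Filled markers had a camera adjusted p under 0.05, squares also held with an estimated correlation, and open markers were not called; the immediate early list had medians of -0.98, -1.44 and -1.69 with IN10018, crizotinib and the combination.

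Genes called with IN10018 were mostly also called with crizotinib and with the combination, and genes called with crizotinib mostly with the combination. Of the 59 higher and 27 lower genes with IN10018, 57 and 25 were called the same way with crizotinib, where independent calls would give 11.8 and 4.76. With the combination 55 and 25 were shared, against 19.9 and 7.85 for independent calls. Of the 3421 higher and 3014 lower genes with crizotinib, 3317 and 2955 were shared with the combination, against 1153 and 876. No gene was called in opposite directions. These overlaps hold for the fit of all 12 libraries. A fit of only the 6 IN10018 and control libraries called 1314 genes higher and 879 lower, for which overlaps were not counted. The 3 comparisons used the same 3 control libraries, which alone correlate the changes. Across the 17096 genes, which are not independent replicates, the IN10018 and crizotinib changes had Pearson r = 0.57, against 0.50 in simulations without any treatment effect, and a covariance of 0.074 against 0.020. For IN10018 and the combination r was 0.48 against 0.50, and the covariance 0.094 against 0.020. For crizotinib and the combination r was 0.95 against 0.50, and the covariance 0.357 against 0.020. Part of the excess overlap may come from the shared controls, which at 3 libraries cannot be divided into separate sets of 2.

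The comparison of the combination with IN10018 addressed what crizotinib added to IN10018. FOS (-4.97 ± 0.22, edgeR adjusted p = 1.4e-08) and FOSB (-6.18 ± 0.22, adjusted p = 1.2e-09) fell, as did EGR1 (-1.46 ± 0.16). The RNA of the polypeptide PCSK1N rose by 2.83 ± 0.42, that of complement factor D (CFD) by 2.74 ± 0.33 and that of CCDC85B by 3.09 ± 0.46. MET changed by -1.32 ± 0.16 and PTK2 by -0.96 ± 0.15, the latter no longer called with the within-group axis as a covariate (-0.31). The p53-inducible BBC3, which promotes apoptosis, rose by 1.86 ± 0.26. The list of 27 apoptosis regulators was not called, with 5 higher and 10 lower (median -0.14, camera adjusted p = 0.39). Against protein-coding genes alone the p53 list was not called either (camera adjusted p = 0.73). EdgeR called 5079 genes higher and 4706 lower, 2044 and 1160 at least 2-fold. DESeq2 called 4627 and 4804 and limma-voom 5012 and 4722. Library totals shifted the median by 0.113. After the offset 5612 of the 9785 genes were called the same way and 323 the opposite way. With the within-group axis as a covariate 200 and 306 genes were called, and PCSK1N (1.74), CCDC85B (1.23) and BBC3 (0.89) were not.

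Of 44 S phase genes 31 fell and 1 rose, 32 and 1 adjusted over the list alone, with DTL at -1.21 ± 0.14, RRM2 at -1.52 ± 0.18 and the helicase gene BRIP1 at -1.51 ± 0.18 (median -0.50, camera adjusted p = 4.7e-09, 0.14 with an estimated correlation). Genes of G2 and mitosis had 41 of 57 lower and 4 higher, with ECT2 at -1.52 ± 0.18 (median -0.51, 0.43 with an estimated correlation). Ribosomal protein genes had 40 of 50 higher and 1 lower, with RPL13 at 2.19 ± 0.30 and RPS15 at 1.34 ± 0.20 (median 0.56, adjusted p = 4.7e-09, 0.48 with an estimated correlation). The immediate early list had 14 of 22 lower and 3 higher (median -0.77, adjusted p = 1.2e-06, 0.14 with an estimated correlation). Mitochondrially encoded genes had 12 of 13 lower (median -1.39, adjusted p = 0.00036, 0.53 with an estimated correlation), with MT-ATP8 at -3.32 ± 0.58 and the leucine transfer RNA gene MT-TL1, outside the list, at -2.70 ± 0.51. The median of the mitochondrially encoded list turned to 0.17 with the within-group axis as a covariate. YAP/TAZ-TEAD targets had 12 of 20 lower and 2 higher, with CCN1 at -1.01 ± 0.13 and MYOF at -1.20 ± 0.16 (median -0.37, adjusted p = 0.0091, 0.38 with an estimated correlation). Cholesterol synthesis genes had 12 of 24 higher and 3 lower, 13 and 3 adjusted over the list alone. The mevalonate enzyme MVD rose by 1.97 ± 0.29 and the sterol sensor gene INSIG1 by 1.04 ± 0.15. The list median was 0.33 (adjusted p = 0.014, 0.14 with an estimated correlation), and its call was lost without combination library 3 (0.26). NRF2 targets had 13 of 22 higher and 5 lower, with AKR1C2 at 0.89 ± 0.09 and the ferritin light chain FTL at 0.91 ± 0.12, which was 0.19 and not called with the offset (median 0.54, adjusted p = 0.022, 0.43 with an estimated correlation). That call was also lost without combination library 3 (0.46) and with the replicate number as a block (0.54, adjusted p = 0.0502). The focal adhesion list had 16 of 30 lower and 7 higher, with ITGA1 at -1.41 ± 0.21 (median -0.38, adjusted p = 0.032, 0.48 with an estimated correlation), and lost its call without combination library 1 (-0.36) and against protein-coding genes. In the thioredoxin list 7 of 23 rose and 8 fell, and the list was not called (median -0.04, mean 0.08, test direction higher, adjusted p = 0.89).

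The comparison of the combination with crizotinib addressed what IN10018 added. Only FOS (-3.48 ± 0.21, edgeR adjusted p = 1.6e-06) and FOSB (-3.11 ± 0.21, adjusted p = 3.9e-06) were called, both lower, and both remained called in every alternative run. These p-values also rest on the spread of the control and IN10018 libraries, which varied less. In a fit of only the 6 libraries compared, without a block, the smallest edgeR adjusted p was 0.0018. FOS went from 145 ± 24.1 CPM with crizotinib to 13.0 ± 4.40 CPM with both drugs, and FOSB from 23.3 ± 4.72 to 2.70 ± 0.278 CPM. DESeq2 called 16 genes higher and 5 lower, limma-voom 0 and 2, and 3697 genes had an unadjusted p under 0.05 with edgeR. With the replicate number as a block the counts were 90 higher and 4 lower in the 12 libraries, and 1987 and 1803 in a fit of the 6 libraries compared. The same-number crizotinib and combination libraries had residual correlations of 0.22, 0.62 and 0.27, and for each of the 3 numbers the combination library had the higher score on the first component and the lower mitochondrial share. Without crizotinib library 2 the counts were 2614 higher and 3026 lower, and without combination library 1 there was 1 higher gene. The following differences were not called, each with adjusted p = 0.21. EGR1 differed by -0.72 ± 0.16, MCM2 by -0.58 ± 0.14, CCNA2 by -0.49 ± 0.15, TXNRD1 by -0.40 ± 0.14, MYOF by -0.54 ± 0.16 and RPL13 by 1.00 ± 0.29. All 6 were called without a filter on low counts, without crizotinib library 2 (adjusted p = 0.0044 to 0.0064), without the number 2 libraries of both groups, and with a replicate block in the 6 libraries. In that last fit EGR1 had adjusted p = 0.00053, MCM2 0.0018, CCNA2 0.0023, TXNRD1 0.014, MYOF 0.0035 and RPL13 3.6e-06, and 23 of 26 named genes gained a call. EGR1 alone was also called with a replicate block in the 12 libraries (0.035) and by DESeq2 (0.036). Whether these genes differ therefore depends on the fit.

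Camera called 5 lists in this comparison and 0 of them with an estimated correlation (adjusted p = 0.74 for each). With a replicate block in the 6 libraries compared, at the preset correlation, these 5 kept their call and 1 further list gained one. Mitochondrially encoded genes had a median of -0.96 with no gene called over all genes and 11 of 13 lower adjusted over the list alone (camera adjusted p = 3.1e-06). S phase genes had a median of -0.19 and genes of G2 and mitosis -0.20 (both adjusted p = 3.9e-05), with no member called over all genes in either list. The immediate early list had 2 of 22 lower, FOS and FOSB, and 3 adjusted over the list alone (adjusted p = 0.00027). Its median was -0.02 and its mean -0.41, and under library totals the median was 0.04 while the test stayed lower. Ribosomal protein genes had a median of 0.16 and no call (adjusted p = 0.0039), and that list was not called without crizotinib library 1 (0.06) or combination library 2 (0.05).

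The interaction term asked whether the change with both drugs differed from the sum of the single-drug changes on the log2 scale. FOS fell more than the sum, with a term of -2.26 ± 0.27 (edgeR adjusted p = 0.0054) that remained called in every alternative run. Its levels were 945 ± 116 CPM in control, 407 ± 28.8 with IN10018, 145 ± 24.1 with crizotinib and 13.0 ± 4.40 with both. FOSB had a term of -1.80 ± 0.26 (adjusted p = 0.016), with 483 ± 102, 196 ± 13.0, 23.3 ± 4.72 and 2.70 ± 0.278 CPM. The FOSB term was not called without IN10018 library 1 (-1.75), 2 (-1.84) or 3 (-1.86), without combination library 1 (-1.83) or 3 (-1.76), or with limma-voom (-1.80). TRIB1 fell less than the sum (1.72 ± 0.18, adjusted p = 0.0031) and remained called in every alternative run, with 43.9 ± 6.58 CPM with crizotinib and 44.2 ± 3.38 with both. NR4A2 had 1.49 ± 0.19 (adjusted p = 0.0074), with 23.0 ± 0.671 and 24.5 ± 2.68 CPM, and was not called without IN10018 library 2 (1.44), IN10018 library 3 (1.46) or crizotinib library 3 (1.44). ATF3 had 3.01 ± 0.43 (adjusted p = 0.016), with 0.664 ± 0.232 CPM with crizotinib and 0.662 ± 0.272 with both. Both levels are low, so the ATF3 term cannot tell a lesser joint effect from a level that cannot fall much further. The ATF3 term was not called without control library 1 (3.04) or 2 (2.91), IN10018 library 2 (2.92) or 3 (2.92), crizotinib library 3 (3.07), or combination library 1 (2.94) or 2 (2.71).

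**Figure D4:**
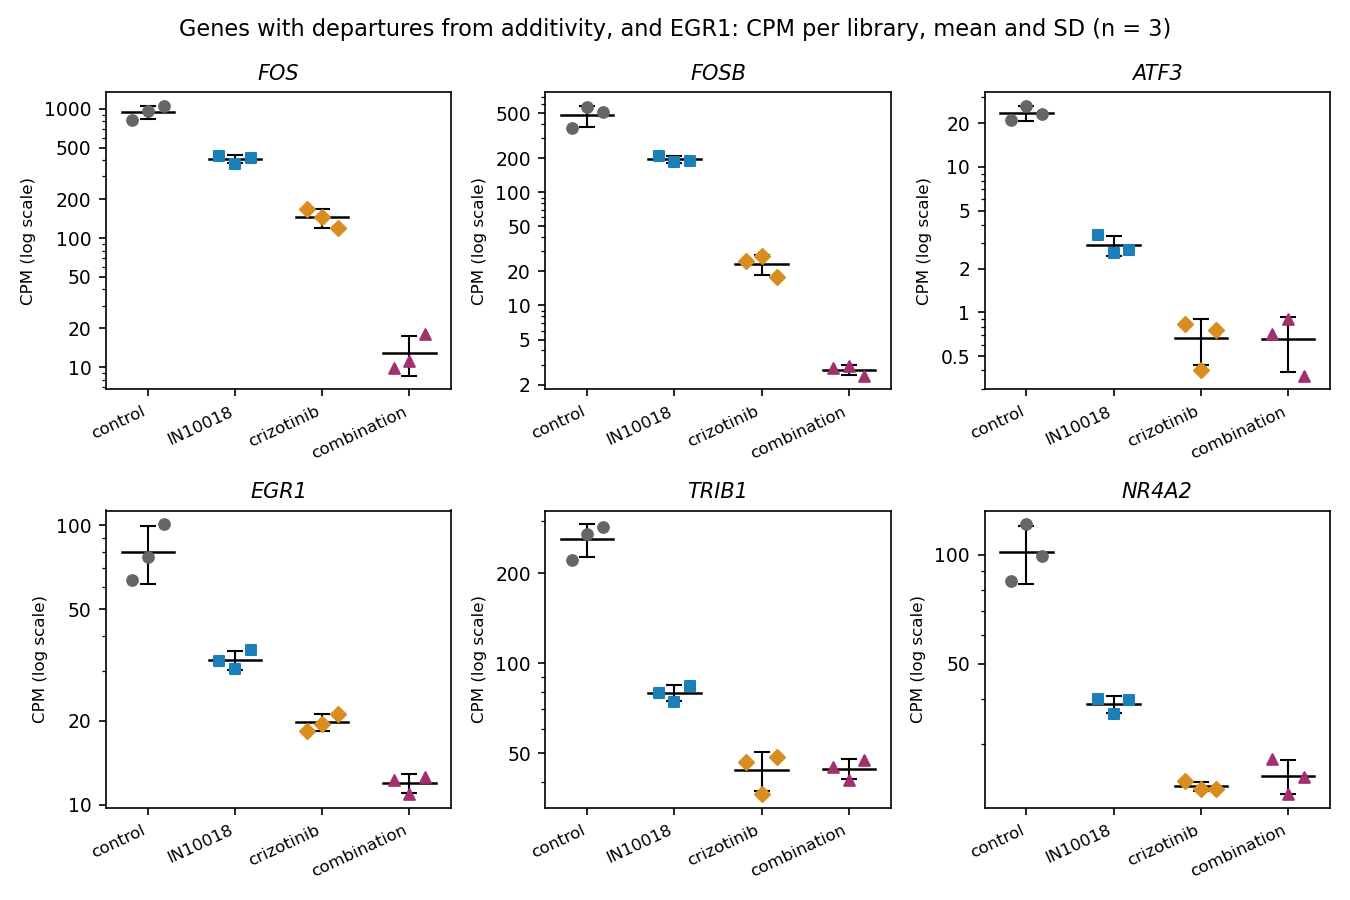
Levels in CPM on a log axis of FOS, FOSB, ATF3, EGR1, TRIB1 and NR4A2 in the 4 groups, with points as libraries and group means with the SD. FOS and FOSB were lower with both drugs (13.0 and 2.70 CPM) than with crizotinib (145 and 23.3 CPM), whereas TRIB1 had 43.9 CPM with crizotinib and 44.2 CPM with both.

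The zinc finger gene ZNF428 had an interaction of 2.89 ± 0.42 (edgeR adjusted p = 0.016), with means of 18.8, 7.55, 13.0 and 39.1 CPM in control, IN10018, crizotinib and combination libraries. The ribosomal protein pseudogene RPL13P12, whose reads can be shared with its parent gene, had 3.59 ± 0.52 (adjusted p = 0.016), with 9.61, 2.79, 6.21 and 22.2 CPM. Both were not called without any one of control libraries 1 and 2, the 3 IN10018 libraries, crizotinib library 3 or combination library 3, with values of 2.79 to 2.98 for ZNF428 and 3.34 to 3.91 for RPL13P12. LINC01315 (1.99 ± 0.33) and the zinc transporter gene SLC39A3 (1.80 ± 0.30) had adjusted p = 0.046. LINC01315 was called only in the fits without crizotinib library 2 among those that left out 1 library, with values of 1.72 to 2.19 in the others. SLC39A3 was called only in the fits without control library 3 or crizotinib library 2, with values of 1.60 to 1.87 in the others. The count was 10 higher and 2 lower genes, the other 3 called genes were higher, and 1367 genes had an unadjusted p under 0.05. DESeq2 called 46 and 17 and limma-voom 7 and 1. Without crizotinib library 2 the counts were 392 and 413. Higher calls numbered 2 without control library 1, 2 without control library 2, 3, 1 and 1 without IN10018 libraries 1, 2 and 3, 1 without crizotinib library 3, 5 without combination library 2 and 3 without combination library 3. There was 1 lower call without each IN10018 library and without combination library 1 or 3.

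Camera called 12 lists for the interaction, 11 as higher, and 2 of them with an estimated correlation. Against protein-coding genes alone 7 were called, and with an estimated correlation there the immediate early and NF-kB lists had adjusted p = 0.079. The immediate early list had 3 of 22 genes higher, 2 lower and 17 not called, 12 and 2 adjusted over the list alone (median 0.59, adjusted p = 6.3e-09, 0.050 with an estimated correlation). Its higher members were ATF3, TRIB1 and NR4A2 and its lower members FOS and FOSB. The NF-kB and cytokine list had no called member, 3 higher adjusted over the list alone (median 0.28, adjusted p = 0.00046, 0.050 with an estimated correlation). Ribosomal protein genes had a median of 0.26 (adjusted p = 6.3e-09, 0.29 with an estimated correlation) and mitochondrially encoded genes one of -0.94 (adjusted p = 0.00023, 0.44 with an estimated correlation), both without a called gene. The ERK output list had a median of 0.20 and no called gene (adjusted p = 0.0024, 0.23 with an estimated correlation), and lost its call without crizotinib library 2 (0.15). In the ATF4 list ATF3 was the only called member, and in the FOXO list TRIB1.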

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

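The tests of a wrong label and of crizotinib library 2 as the source of the FOS and FOSB terms were chosen after the results they concern had been seen, as was the per-kilobase part of the test for genomic DNA. Single libraries were not tested for distance from their group, which holds 3 libraries in each case. The results below were picked because the change with both drugs differed from the sum of the single-drug changes, by the interaction term.

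For single genes the interaction log2 fold changes were 3.59 for RPL13P12, 3.01 for ATF3, 2.89 for ZNF428, 1.99 for LINC01315, 1.80 for SLC39A3, 1.72 for TRIB1 and 1.49 for NR4A2. They were -1.80 for FOSB and -2.26 for FOS. The ATF3 term rests on low levels with crizotinib and with both drugs, which left little room for a further fall. For lists the medians were 0.26 for ribosomal protein genes, 0.59 for immediate early genes, -0.94 for mitochondrially encoded genes, 0.28 for NF-kB and cytokines, 0.20 for ERK output, 0.076 for cholesterol synthesis, 0.13 for STAT3 targets, 0.11 for NRF2 targets, 0.048 for the ATF4 list, 0.11 for MYC and ribosome biogenesis, 0.088 for oxidative phosphorylation and 0.073 for FOXO targets. With an estimated correlation only the immediate early and NF-kB lists stayed called, both at adjusted p = 0.04998. The others had 0.089 for cholesterol synthesis, 0.16 for STAT3 targets, 0.23 for ERK output and for MYC and ribosome biogenesis, 0.28 for NRF2 targets, the ATF4 list and FOXO targets, 0.29 for ribosomal protein genes and oxidative phosphorylation, and 0.44 for mitochondrially encoded genes. Among 100 regroupings of the 12 libraries, the real one included, 3 gave at least the real 12 called genes. The highest of the others called 6105 genes, and 96 called none. These regroupings mix treatment groups that differ in many genes, which widens the spread within each, so they cannot show whether the interaction calls came from random grouping.

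FOS and FOSB fell more with both drugs than the single-drug changes add up to. After each library's trend in GC content and length was removed, the FOS term was -2.31 ± 0.28 and the FOSB term -1.91 ± 0.23, which argues against such bias as the whole cause. Without crizotinib library 2 the FOS term was -2.26 ± 0.26 and the FOSB term -1.68 ± 0.25, so that library is not the source. A joint effect of the drugs on FOS and FOSB was not tested further and stays open. A change in the timing of induction and unequal handling of cultures also stay open, since the labels give 1 time point and no culture record.

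Crizotinib library 2 lies among the combination libraries on the first principal component. Its FOS level of 145 CPM was 8.08 times that of the highest combination library, at 18.0 CPM. FOS was itself called between these groups with this library labelled crizotinib, so the gene was not independent of the label tested. The FOS level is therefore only weak support against a combination library under a wrong label. Without this library, 2614 genes were higher and 3026 lower with the combination than with crizotinib. The levels of crizotinib library 2 on those genes were not examined. With GC and length trends removed its score was 42.3, still above the lowest combination library at 31.5. Such trends are therefore not the whole cause of its place. Before the removal its score of 57.8 lay above combination library 1 at 56.3, and afterwards below that library at 45.3. With mitochondrially encoded genes left out the score of crizotinib library 2 was 57.3, against 37.5 for the lowest combination library. At most 37 of the 17096 genes behind the component are mitochondrially encoded, and the values were already TMM-scaled. Leaving these genes out could hardly move the score, so it cannot decide on the mitochondrial share. No biological explanation was tested, because the labels give nothing that sets this library apart. A difference in culture state, exposure or RNA quality stays open.

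Long non-coding transcripts sat higher with IN10018, with a median 0.41 above that of protein-coding genes. Reads over 382 olfactory receptor genes, which should be silent, numbered 40 in control and 50 with IN10018, a ratio of 1.25 in reads scaled to library totals. That ratio lies between the bounds first set, at 1.2 and 1.5, and decides nothing by itself. Per kilobase, the 95% upper limit of the olfactory reads was 0.00576 of the median gain of long non-coding genes, which argues against genomic DNA. Removing GC and length trends left a difference of 0.36, a ratio of 0.881 to the value before, so such bias is not the whole cause. A change in RNA processing or turnover with IN10018, or unequal RNA quality, may underlie the shift and was not tested.

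Other splits of the 6 libraries of a comparison were counted for the genes called in a fit of those 6 alone. With 10 splits a share under 0.05 cannot be reached, so only the values are given. Every other split also mixes the groups compared, which widens the spread within each side where those groups differ. Low counts in the other splits therefore cannot show that the real calls did not come from random grouping. IN10018 against control called 2193 genes, with 1 as the highest of the other splits, and 1 of 10 splits reached the real value. Crizotinib against control called 4930, the combination against control 10353 and the combination against IN10018 9651, each with 0 as the highest of the others and 1 of 10 splits as large. The combination against crizotinib called 2 genes, 2 of 10 splits were as large, and the highest other called 3793. That split set crizotinib libraries 1 and 3 and combination library 3 against crizotinib library 2 and combination libraries 1 and 2, and so points to a structure of the samples. With a replicate block in the 6 libraries the real comparison called 1987 higher and 1803 lower genes, although the labels do not say that the numbers pair the libraries.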

How the results depend on the processing

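The offset for GC content and length, the removal of mitochondrially encoded genes, the removal of the number 2 libraries, the within-group axis covariate, the block in 6 libraries and the list tests against protein-coding genes were added after seeing the data, and the other alternatives were planned. Of the values of named genes under the alternatives, 14475 kept their direction and their side of the threshold, 468 were no longer called, 354 were newly called and 25 reversed. For list tests these numbers were 4975, 175, 200 and 3. The stricter filter ended 8 list calls and added 1, and no filter on low counts ended 2 and added 24. DESeq2 size factors ended 1 list call and added 1. The lists concerned are not all named in the text. Counts of called genes stayed within 1.5 times in 212 cases and moved further in 88. The 3 correlations of fold changes were each run under 3 alternatives, and all 9 cases counted as the same. That label allows a small shift in r. It does not show that the excess for IN10018 and crizotinib, 0.57 against a simulated 0.50, is stable. Every alternative fixed beforehand was run. Except where stated, the cause of a difference was not tested. Depth limits mainly genes of few reads, and ROS1, with 0 reads, cannot be compared.

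Leaving out 1 library at a time gave 1 to 169 higher and 6 to 54 lower genes for IN10018 against control, and 1354 to 4468 higher and 1372 to 3507 lower for crizotinib against control. For the combination against crizotinib it gave 0 to 2614 higher and 2 to 3026 lower, and for the interaction 1 to 392 higher and 1 to 413 lower. The highest counts of the last 2 comparisons and of IN10018 against control came without crizotinib library 2.

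Library totals gave 1948 lower genes for crizotinib against control. Without a filter on low counts there were 304 higher and 75 lower genes for IN10018 against control, 772 and 972 for the combination against crizotinib and 175 and 124 for the interaction. With a replicate block there were 188 and 43 for IN10018 against control, 90 and 4 for the combination against crizotinib and 21 higher for the interaction. In a fit of only the 6 libraries compared, IN10018 against control had 1314 and 879. With a replicate block in those 6, the combination against crizotinib had 1987 and 1803. A minimum of 2-fold, which by construction lowers counts, left 30 higher genes for IN10018 against control, 1205 and 246 for crizotinib against control, 2889 and 1437 for the combination against control and 2044 and 1160 for the combination against IN10018.

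DESeq2 called 114 and 67 genes for IN10018 against control, 16 and 5 for the combination against crizotinib and 46 and 17 for the interaction. Limma-voom called 39 higher genes for IN10018 against control and 1 lower for the interaction.

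With the offset for GC content and length there were 181 and 61 genes for IN10018 against control and 17 and 4 for the interaction. Of the genes called without it, 3899 of 6435 were called the same way for crizotinib against control and 3 the opposite way. These numbers were 6940 of 10729 and 342 for the combination against control, and 5612 of 9785 and 323 for the combination against IN10018. It reversed ZEB1 with crizotinib (0.039). In the combination against control it reversed NAGLU (-0.087), HES6 (-0.24), NOTUM (-0.19), MST1R (-0.15), TEAD2 (-0.37), TEAD3 (-0.17) and TEAD4 (-0.63). In the combination against IN10018 it reversed CEBPB (-0.29), HSPH1 (0.024), IRF7 (-0.081), NAGLU (-0.015), ZEB2 (0.0063), HES6 (-0.057), TAGLN2 (-0.0013) and NOTUM (-0.23). The direction of these genes is therefore not settled.

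Without the number 2 libraries of crizotinib and combination there were 629 and 235 genes for IN10018 against control, 1877 and 2475 for the combination against crizotinib and 933 and 984 for the interaction. The within-group axis as a covariate gave 871 and 541 for IN10018 against control, 1103 and 1066 for crizotinib against control, 882 and 933 for the combination against control, 200 and 306 for the combination against IN10018 and 83 and 41 for the interaction. Because the axis runs along the crizotinib and combination changes, it can remove part of the treatment effect. It reversed the median of the mitochondrially encoded list with crizotinib (0.39), with the combination (0.26) and in the combination against IN10018 (0.17). In the combination against control it reversed MT-ND2 (0.30), MT-ND4 (0.23), JAG2 (-0.12), HES6 (-0.19) and TXN (0.10). In the combination against IN10018 it reversed FN1 (0.070), MT-ND2 (0.17), MT-ND4 (0.19) and JAG2 (-0.033).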

Other observations

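The antigen presentation list was not called with either crizotinib or the combination in the main test, although single members were. With crizotinib 8 of 17 rose and 1 fell, 10 and 1 adjusted over the list alone (median 0.48, camera adjusted p = 0.058, 0.38 with an estimated correlation), with HLA-E at 0.59 ± 0.13. Against protein-coding genes alone the list was called higher with crizotinib (camera adjusted p = 0.025), but not with an estimated correlation there (0.40). With the combination 10 rose and 4 fell (median 0.55, adjusted p = 0.21, 0.50 with an estimated correlation). Of 10 tested adipocyte markers, listed because of the description label, 4 rose and 2 fell with the combination, 5 and 2 adjusted over the list alone (median 0.64, adjusted p = 0.39). CFD (1.92 ± 0.32), the lipid droplet gene PLIN1 (1.33 ± 0.23) and the lipase gene LIPE (0.91 ± 0.17) rose, whereas PPARG, the regulator of fat cell formation, changed by -0.95 ± 0.14. With the within-group axis as a covariate, CFD (0.42), PLIN1 (1.14), LIPE (0.15) and PPARG (-0.32) were not called.

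Immediate early genes were not uniform with the combination. IER2 rose by 1.32 ± 0.26, IER3 by 0.45 ± 0.13 and GADD45B by 0.43 ± 0.14, while JUN changed by -2.69 ± 0.20, DUSP1 by -1.74 ± 0.17 and ZFP36 by -1.847 ± 0.26. These 6 were picked from the list after their values were seen.

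Of the epithelial lists, 5 of 26 gastric epithelium genes, 1 of 26 intestinal epithelium genes and 19 of 32 epithelial junction genes passed the filter. Markers of other cell types were read as a description. The collagen gene COL3A1 was abundant in each group, at 6046, 5546, 6044 and 5443 CPM in control, IN10018, crizotinib and combination libraries, and POSTN had 670, 594, 424 and 311 CPM. The fibroblast markers FAP and THY1 had 0 and 2 reads in all 12 libraries. CD14 had 20.6, 18.7, 30.1 and 31.4 CPM. Of the endothelial markers PECAM1 had 6.51, 9.23, 16.4 and 27.1 CPM, CDH5 13.6, 15.4, 9.16 and 9.44 CPM and ERG 4.005, 3.38, 3.43 and 2.44 CPM, and VWF and KDR had 2 and 0 reads in all 12 libraries, whereas the leukocyte genes CD3E and CD3D had 0 reads.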
